A study of Sargassum vulgare with 6 samples.

How the data were processed

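RNA was sequenced from apical tissue of Sargassum vulgare, a brown macroalga, collected around Ischia Island at a site acidified by natural carbon dioxide vents and at a control site. Each of the 6 libraries was made from a pool of 3 thalli with a stranded total RNA kit, and there were 3 libraries per site. The libraries shared a single sequencing lane, per the series' design text. Each library was assigned to its site by the location given in its labels, and its replicate number was taken from its title.

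The deposited files were 2 tables of FPKM (fragments scaled by transcript length and by the mapped fragments of the library), one per site, with 3 libraries each and the same 67131 transcripts in the same order. Per the submitters' processing notes, Bowtie2 and RSEM 1.1.21 were used; their roles and settings, the assembler, the annotation and any filtering are not given in the sources used here. The transcript names carry the site of the assembly that each came from and an assembly component, a group of sequences that an assembler takes as forms of 1 gene. By these names 42918 transcripts came from an assembly of the acidified site and 24213 from one of the control site, in 33911 components. Components were numbered separately in each assembly, so a gene assembled at both sites can appear under different names. The tables do not pair transcripts with gene names, functions or sequences, and no reference genome was used. Lists of genes by function were fixed before the data were examined, but they could not be tested without names.

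Values under 10 in every library were whole multiples of 1 step per library, within 0.0005, for 100% of the values above 0. The step ranged from 0.00886 to 0.0116, and divided by 0.01 the 6 steps had a product of 1.00. The deposited FPKM therefore have the form of values rounded to 2 decimals and then multiplied by 1 factor per library that was set over all 6 libraries together, although no label records such a step. Both tables were analysed in 1 fit, as fixed before the data were examined, because FPKM is scaled within each library. The step is that of the rounding, not the worth of 1 read, so read counts were not recovered. Sequencing depth is not given. The ratio between libraries that was most frequent among low values, after the factors were removed, gave an estimate of relative depth, which ranged from 0.749 in acidified library 2 to 1.05 in acidified library 1, with control library 1 set to 1. Without counts, no counting interval could be given. Fragments shared by near-identical sequences, such as forms of a component or copies assembled at both sites, are divided between them by the estimate, so single transcripts with close copies are uncertain.

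Transcripts were tested if their FPKM was at least 1 in at least 3 of the 6 libraries, which kept 5399, 2720 from the acidified-site assembly and 2679 from the control-site assembly. The acidified site was compared with the control site on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with a variance trend and robust fitting, and p-values were two-sided and adjusted by the Benjamini-Hochberg method. An adjusted p under 0.05 counted as a call. Fold changes are differences on the log2(FPKM + 1) scale, which understates changes of low transcripts. The same fit was made for FPKM summed over each component, and for the log2 value of a transcript minus that of its component (isoform usage) in components with 2 or more tested transcripts. Single values per library were compared with an exact two-sided permutation test, for which 3 libraries against 3 cannot give a p under 0.10. Each site is a single location, so acidification and any other difference between the locations are not separable in this design.

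The named transcripts are the 2 with the largest rise and the 2 with the largest fall among called transcripts whose 3 values at one site all lay above the 3 at the other, a rule fixed before the data were examined for the case in which names are not given. The design, the threshold and most alternatives were also fixed then. The alternatives were pseudocounts of 0.1 and 5, no filter, a mean FPKM of at least 5, rescaling each library to the same sum, median ratio scaling, quantile normalization, limma without trend or robust fitting, the replicate number as a block, a fold of at least 2, and leaving out each library in turn. Removing the per-library factor was added after the data were seen, as were the ranks of the named transcripts under the alternatives, plain FPKM shares of a component and the comparisons by assembly of origin and by abundance class.

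The fits were tested on simulated data with 200 changed rows. The noise was normal and independent between rows, with the spread that limma had estimated for each row, so it followed the assumptions of the test. Rows that vary together and single libraries far from the others were not simulated. The shares of false calls below are therefore not the error rate of the real calls. Over 5399 transcripts, 38% of changes of 1 on the log2 scale, 90% of those of 2, 100% of those of 3 and 98% of those of 4 were recovered, and 5.23% of all calls were false. Over 5176 components the shares were 44%, 94%, 100% and 100%, with 5.06% of calls false. Over the 1067 transcripts of the isoform test they were 42%, 86%, 100% and 100%, with 4.65% of calls false. There the simulation made 172 calls and the real isoform test 22, and more calls make the adjusted threshold less strict. The recovered shares may therefore be too high for the real isoform test.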

Results

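Transcript abundance was measured in Sargassum vulgare, a canopy-forming brown alga, growing at a site off Ischia acidified by natural carbon dioxide vents and at a control site off the same island, to ask which transcripts differ between algae living under the 2 conditions. There were 3 libraries per site, each a pool of 3 thalli. The deposited FPKM summed to between 764917 and 895218 in the control libraries and between 750020 and 1048696 in the acidified libraries, and the number of reads behind them is not known. Of the 67131 listed transcripts, 32193 (48.0%) were at 0 in all 6 libraries. The 5399 transcripts that passed the abundance filter held between 99.1% and 99.5% of the summed FPKM of each library.

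Libraries of one site resembled each other more than libraries of different sites. Across the tested transcripts, Pearson's r of log2(FPKM + 1) lay between 0.964 and 0.976 within the control site, between 0.962 and 0.971 within the acidified site, and between 0.921 and 0.943 for the 9 pairs of libraries from different sites. Spearman's rho was 0.830 to 0.881, 0.836 to 0.863 and 0.726 to 0.785 respectively. These values are across transcripts, which are not independent replicates. The first principal component held 52.3% of the variance and separated the sites, with scores of -31.4, -30.0 and -30.4 in the control libraries and 40.2, 30.2 and 21.4 in the acidified libraries 1, 2 and 3. The median SD of a transcript among the 3 libraries of a site was 0.33 at the control site and 0.34 at the acidified site on the log2 scale. The median absolute difference between the site means was 0.39. The SD is that of single libraries, and means of 3 libraries vary less, so these values are not directly comparable.

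More transcripts were listed at 1 FPKM or more in the acidified libraries, in a table that holds 42918 transcripts from the acidified-site assembly and 24213 from the control-site assembly. FPKM reached 1 for 5692 ± 31.5 transcripts (SD, n = 3) in the acidified libraries and for 5355 ± 141 (SD, n = 3) in the control libraries, a difference of 337 with no overlap between the sites (exact permutation test, p = 0.10, the smallest that 3 against 3 allows). The difference went with the assembly of origin: among transcripts of the acidified-site assembly 3124 ± 118 were at 1 FPKM or more in the acidified and 2545 ± 90.4 in the control libraries, and among those of the control-site assembly 2568 ± 87.7 and 2810 ± 50.5 (SD, n = 3 each; exact permutation p = 0.10 for both). The count of transcripts above 0 was 18574 ± 961 against 15564 ± 341 (SD, n = 3 each; exact permutation p = 0.10). A few transcripts dominated every library. The 100 highest held 56.7% ± 5.16 of the summed FPKM at the acidified site and 51.4% ± 2.26 at the control site (SD, n = 3 each), which overlapped (exact permutation p = 0.30). The 10 highest held 17.1% ± 3.44 and 11.6% ± 1.64 (SD, n = 3 each; exact permutation p = 0.10). Of the 100 transcripts highest on average at each site, 74 were the same.

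**Figure D1:**
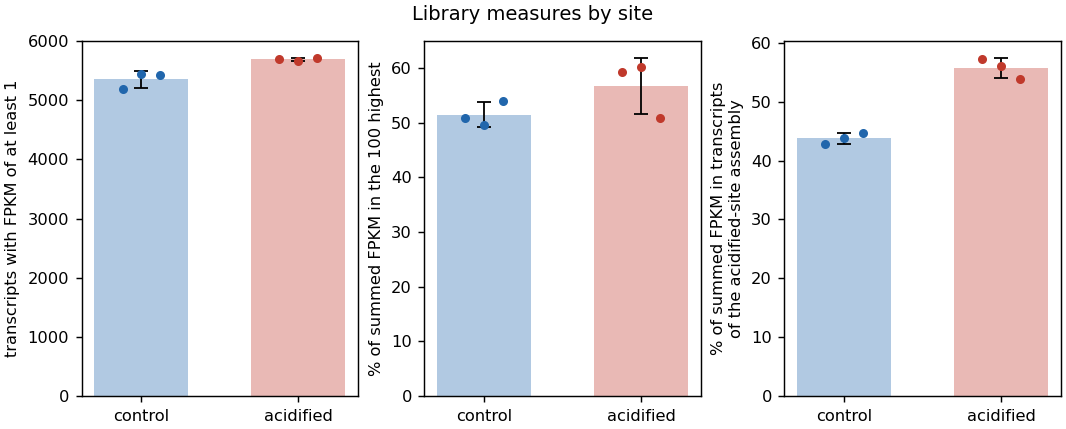
Number of transcripts with FPKM of at least 1, percent of summed FPKM in the 100 highest transcripts, and percent of summed FPKM in transcripts of the acidified-site assembly. Bars are means, error bars the SD and points the 3 libraries of each site; the sites do not overlap in the first measure (5355 against 5692) and the third (43.8% against 55.7%), and they overlap in the second.

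Between the sites, 414 of 5399 transcripts (7.67%) differed in limma's test at an adjusted p under 0.05, of which 222 were higher and 192 lower at the acidified site. Of the called transcripts, 213 of the higher and 184 of the lower changed by at least 1 on the log2(FPKM + 1) scale. By at least 2 changed 68 and 32, and by at least 3 changed 28 and 11. In the simulated data only 38% of changes of 1 were recovered, so the sizes of called changes in part reflect the threshold. The median change was 1.57 among the higher and -1.45 among the lower transcripts, and 0.02 over all tested transcripts. The 222 higher transcripts together held 6.34% ± 1.02 of the summed FPKM at the acidified site and 1.73% ± 0.03 at the control site (SD, n = 3 each). The 192 lower transcripts held 3.28% ± 0.86 and 9.46% ± 0.62. These shares describe transcripts picked for their difference and are not a further test. In all 414 the 3 values at one site lay above the 3 at the other, as in 29.1% of all tested transcripts, where chance gives 10%. The count depended on the filter, the pseudocount and single libraries. Without a filter on low values 40 transcripts were higher and 26 lower, with a pseudocount of 0.1 they were 142 and 126, and with the replicate number as a block 141 and 101. The count was 226, 190 and 136 without control library 1, 2 and 3, and 170, 125 and 394 without acidified library 1, 2 and 3. No sign changed among the 414, but without overlap between the sites no sign can change when 1 library is left out.

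**Figure D2:**
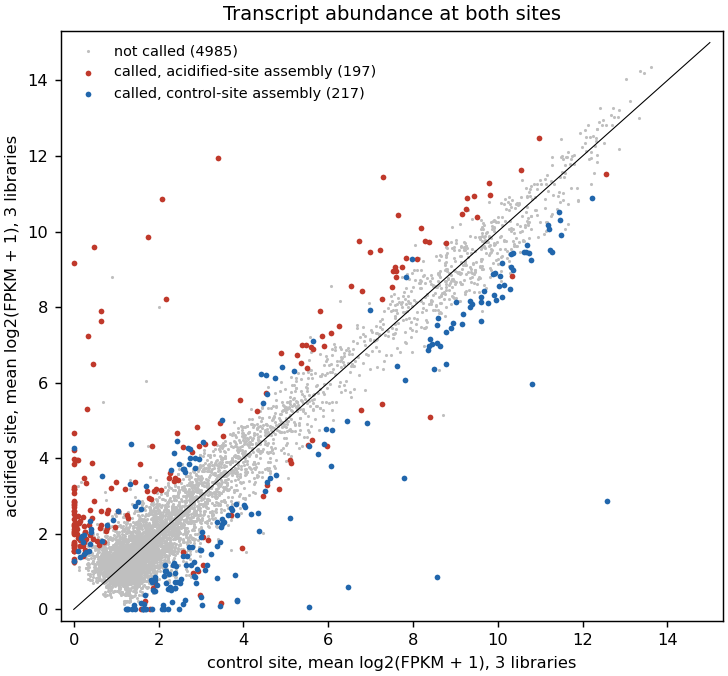
Mean log2(FPKM + 1) of the 5399 tested transcripts over 3 libraries at the control site (x axis) and 3 at the acidified site (y axis), with the line of equal abundance. Red and blue points are called transcripts (adjusted p under 0.05) from the acidified-site and the control-site assembly; 169 of the 222 above the line are red and 164 of the 192 below it are blue.

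On the log2(FPKM + 1) scale the largest rise over all libraries was that of Sample_MAC_c86762.graph_c1_seq3, a transcript of the acidified-site assembly, although its rank depended on the pseudocount and on single libraries: it was first in 11 of 16 alternatives and 5th with a pseudocount of 5. It was listed at 0 in all 3 control libraries and at 685, 603 and 447 FPKM in acidified libraries 1, 2 and 3, a change of 9.16 ± 0.25 (SE) on the log2(FPKM + 1) scale (limma adjusted p = 1.04e-07). The sum of its component of 7 listed transcripts was 0.925 ± 0.515 FPKM at the control site and 579 ± 121 at the acidified site (SD, n = 3 each, limma adjusted p = 1.95e-08). No other member exceeded 0.755 FPKM in any library. At the acidified site the sum is therefore nearly this transcript alone, and it does not show that the other forms differed. Next was Sample_MAC_c87845.graph_c0_seq1, which was first in 2 and second in 12 of the 16 alternatives. It was at 0.614, 0.694 and 0 FPKM in the control libraries and at 1337, 998 and 333 in the acidified libraries, a change of 9.09 ± 0.49 (SE; limma adjusted p = 3.60e-05). Its component did not pass the test, at 2717 ± 523 FPKM at the control site and 2317 ± 984 at the acidified site (SD, n = 3 each; limma adjusted p = 0.61). The other 2 transcripts of that component had log2 differences of -0.92 and -1.06 (limma adjusted p = 0.11 for both).

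The largest fall was that of Sample_MLA_c34559.graph_c0_seq1, from the control-site assembly and the single member of its component. It stood at 6353 ± 2339 FPKM at the control site, 0.752% of the summed FPKM, and at 8.84 ± 9.51 at the acidified site (SD, n = 3 each), a 719-fold lower mean (log2 change -9.70 ± 0.60 SE, limma adjusted p = 0.00014). Sample_MLA_c35298.graph_c0_seq3 was next, with 222, 530 and 464 FPKM in the control libraries and 1.65, 0 and 1.29 in the acidified libraries (log2 change -7.70 ± 0.45 SE, limma adjusted p = 3.61e-05). The other listed transcript of its component was at 238, 58.8 and 31.0 FPKM in the control libraries and at 302, 274 and 278 in the acidified libraries (limma adjusted p = 0.12). The component as a whole fell from 515 ± 66.4 to 286 ± 15.8 FPKM (SD, n = 3 each; limma adjusted p = 0.041). The genes behind these 4 transcripts are not identified here, because the tables carry no gene names.

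**Figure D3:**
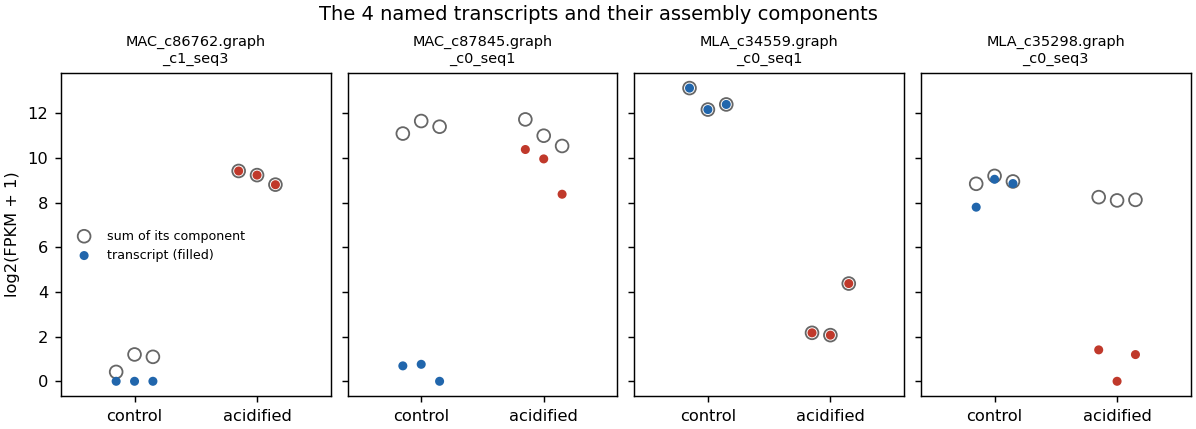
log2(FPKM + 1) of the 4 named transcripts (filled points) and of the sum of their assembly components (open circles) in the 3 libraries of each site. In the second panel from the left the transcript rises from under 1 FPKM to between 333 and 1337 while the component does not pass the test, and in the fourth the transcript falls to under 2 FPKM while the component keeps 286 of 515 FPKM.

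The direction of change went with the assembly a transcript came from. Of the 222 higher transcripts 169 (76.1%) were from the acidified-site assembly, and of the 192 lower transcripts 164 (85.4%) were from the control-site assembly, where 50.4% of tested transcripts were from the acidified-site assembly (Fisher's exact test of direction by assembly, two-sided, p = 4.45e-38, over transcripts that are not independent). Over all tested transcripts the median log2 difference was 0.15 for the acidified-site assembly and -0.09 for the control-site assembly, with the same signs under every scaling tried. Transcripts of the acidified-site assembly held 55.7% ± 1.78 of the summed FPKM in the acidified libraries and 43.8% ± 0.94 in the control libraries (SD, n = 3 each; exact permutation p = 0.10). The association was strong among transcripts abundant at both sites. Of the 82 called transcripts with a mean FPKM of at least 100 at each site, 28 of the 31 higher ones came from the acidified-site assembly and 49 of the 51 lower ones from the control-site assembly.

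Changes were found at every level of abundance. Of the 3449 transcripts with a mean FPKM under 5 over all libraries, 103 were higher and 78 lower at the acidified site (5.25%). Between 5 and 50 FPKM, 60 were higher and 49 lower of 1149 (9.49%), and between 50 and 500 FPKM, 39 were higher and 29 lower of 397 (17.1%). The 404 transcripts at 500 FPKM or more held 86.3% of all summed FPKM, and 20 of them were higher and 36 lower (13.9%).

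Some transcripts were listed at one site only. At 0 in all 3 control libraries and at 1 FPKM or more in all 3 acidified libraries were 44 transcripts, of which 42 came from the acidified-site assembly. Their median was 4.21 FPKM at the acidified site, 7 reached 10 FPKM, and the highest was the transcript named above at 579 FPKM. The opposite pattern was found in 16 transcripts, 14 of them from the control-site assembly, with a median of 2.15 and a maximum of 5.13 FPKM at the control site. These counts depended on the minimum and on single libraries. A minimum of 0.5 FPKM gave 101 and 53 transcripts and one of 5 FPKM gave 6 and 0. The 44 became 73 without control library 1, and 94 and 135 without acidified library 2 and 3, while the 16 became 26 to 45 without any 1 library. Any of the 18 other sets of 3 libraries gave between 0 and 8 such transcripts. Each of those sets holds libraries of both sites, so a transcript found at one site only is not counted in them. An exact 0 in FPKM is an estimate and at these levels does not show that a transcript was absent.

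Summing the transcripts of a component gave a similar picture. Of 5176 tested components, 224 were higher and 220 lower at the acidified site (limma, adjusted p under 0.05), and 180 of the higher and 189 of the lower ones came from the assembly of the site where they were higher. Without a filter on low values 65 components were higher and 34 lower, and with the replicate number as a block 154 and 122. The count of 444 was 282 and 234 without control library 2 and 3, and 245 and 257 without acidified library 1 and 2. Of the 414 called transcripts, 348 belonged to a component called in the same direction and none to one called in the opposite direction. This largely repeats the test of transcripts, since only 1067 of the 5399 tested transcripts shared a component with another tested one. For the others the sum adds only transcripts that did not pass the filter. Components are numbered per assembly, so the sum does not join copies of a gene from both sites. The use of forms within a component was tested for 1067 transcripts of 442 components. On the log2(FPKM + 1) scale, 12 transcripts rose and 10 fell relative to their component, in 20 components, and 13 of these 22 were in components that were not themselves called. The plain FPKM share of the component moved the same way in 21 of the 22, with no overlap between the sites in 20. In the other of these 21, which was among the 12, the component fell from 110 to 0.966 FPKM and the share was 0 in acidified library 3. The 1 that moved the other way rose from a share of 0% to 12.5% while its component rose from 0.246 to 58.0 FPKM. Of the 20 without overlap, Sample_MAC_c95631.graph_c1_seq4 is in this same component, so its control share of 100% rests on 0.246 FPKM. The plain shares were taken for transcripts already called in the same libraries and are not a further test. The 22 included Sample_MAC_c87845.graph_c0_seq1, which rose by 9.39 on the log2 scale relative to its component, from 0.0165% to 36.7% of the component's FPKM (limma adjusted p = 0.00033), and Sample_MLA_c35298.graph_c0_seq3, which fell by 6.86, from 77.3% to 0.336% (limma adjusted p = 0.0014). With the replicate number as a block 2 transcripts rose and 1 fell relative to their component. The count of 22 fell to 3 and 6 without control library 2 and 3, and to 9 and 10 without acidified library 2 and 3.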

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

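The 4 named transcripts kept their direction and an adjusted p under 0.05 in all 16 alternatives tried for each, with the largest limma adjusted p at 0.014. They were picked in these same libraries as the largest called changes without overlap between the sites, so their kept direction is not a further test. The order of the falls was kept in all 16, that of the rises was not. A pseudocount of 0.1 gave 142 higher and 126 lower transcripts, and no filter on low values gave 40 and 26; the unfiltered test also gave 65 higher and 34 lower components, and it includes many more rows. Leaving out 1 library at a time gave 68 to 219 higher and 57 to 175 lower transcripts, 124 to 269 higher and 110 to 234 lower components, and 2 to 12 isoform shares higher and 1 to 12 lower; between 121 and 300 of the calls without a library were among the 414. With the filter applied again to the 5 remaining libraries there were 31 to 142 higher and 42 to 160 lower transcripts. Of the 414, 41 were then not tested without a control library and 92 without an acidified one. Higher calls outnumbered lower ones without control library 1, 2 or 3 (142 and 82, 117 and 86, 85 and 45). The reverse held without acidified library 1, 2 or 3 (39 and 71, 31 and 42, 141 and 160). This reversal came with the reapplied filter. With the filter of the main test kept, higher calls outnumbered lower ones there too (87 and 83, 68 and 57, 219 and 175). A transcript found at 1 site only fails the reapplied filter once that site loses a library. Of the transcripts listed at 0 at one site, a minimum of 0.5 FPKM at the other site gave 101 at the control and 53 at the acidified site, a minimum of 5 FPKM gave 6 and 0, and leaving out a library, which relaxes the criterion, gave 56 to 135 and 26 to 45. The acidified site's excess in the 100 highest transcripts was 3.62 to 8.29 percentage points without single libraries, and with the 1000 highest it turned to -0.14; in detected transcripts it was 256 to 382, and 3010, 757 and 73.3 with FPKM above 0, of at least 0.5 and of at least 5. Where not said, the cause was not tested. No pairing of the libraries by replicate number was seen: deviations of same-numbered libraries from their site means correlated at -0.12, 0.02 and -0.12, and no library correlated best with its own number. Deviations from a mean of 3 libraries constrain each other, so this does not show that the libraries were collected or prepared unpaired. With the number as a replicate block there were 141 higher and 101 lower transcripts, 154 higher and 122 lower components, and 2 and 1 isoform shares. Every other alternative for called transcripts, components and isoform shares left their counts within 1.5 times, the removal of the per-library factor (193 higher, 184 lower; added after the data were seen) included. Under the scalings the share of higher calls was 51.2% to 55.6% and the median of all transcripts -0.04 to 0.02. The alternatives for gene lists were not run, since the tables give no names. Without counts or read numbers, the depth that limits low transcripts is not known.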

Other observations

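The tests of assembly of origin and of the transcripts low in acidified library 2 were chosen after these patterns had been seen. Transcript abundance had a separate high range. By mean FPKM over all libraries, transcripts became rarer from 189 between 25 and 50 FPKM to 79 between 100 and 200 FPKM, then more frequent again, with 153 between 200 and 400, 183 between 400 and 800 and 151 between 800 and 1600.

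Single libraries of both sites held transcripts at levels far from the others of their site. One transcript of the acidified-site assembly was at 12061 FPKM in acidified library 1, at 118 and 10.9 in acidified libraries 2 and 3, and between 2.47 and 3.39 in the control libraries. A second was at 3389, 14.5 and 0.762 FPKM in the acidified libraries and at most 1.16 in the control libraries. Neither passed limma's test (adjusted p = 0.26 and 0.40). At least 4-fold above both other libraries of the site on the log2(FPKM + 1) scale were 15, 5 and 6 tested transcripts in control libraries 1, 2 and 3 and 10, 5 and 21 in acidified libraries 1, 2 and 3. Acidified library 3 had 37 tested transcripts at least 4-fold below both, acidified library 2 had 24, and the other 4 libraries had 10 to 15.

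The direction of change went with the assembly of origin. Among called transcripts with at least 100 FPKM at both sites, 93.9% (77 of 82; exact 95% interval 86.3 to 98.0%) were higher at the site of their own assembly. A transcript that is listed only from the site where it was abundant enough to assemble would not give this, since these were abundant at both; for the 280 called transcripts under 10 FPKM at the lower site, with 78.9% (interval 73.7 to 83.6%), that explanation remains open. The share was lowest in between, at 67.3% (35 of 52; interval 52.9 to 79.7%) for 10 to 100 FPKM at the lower site. A candidate explanation for the abundant ones is that reads of each site were drawn to sequences assembled from that site, for example where the algae of the sites differ in sequence or where near-identical copies from both assemblies share reads. This stays open. The 569 transcripts that were not called and had at least 100 FPKM at both sites had a median log2 difference of 0.26 for the acidified-site and -0.26 for the control-site assembly. The medians were 0.52 apart (SD of random assignments 0.06; permutation p = 0.0001, the smallest that 10000 permutations can give, over transcripts that are not independent). This largely repeats the shift already seen over all 651 tested transcripts of that abundance, with medians of 0.31 and -0.34, and does not decide the question. Real differences in expression combined with a choice of 1 representative per gene by its abundance or length stay open and untested, because this needs the sequences.

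A set of 7 transcripts of the acidified-site assembly, 6 of them called as higher at the acidified site, was low together in acidified library 2. They were picked for a mean of at least 100 FPKM at the acidified and under 50 at the control site and a level at least 4-fold lower in acidified library 2 than in both other acidified libraries; library 1 was 12.8 to 40.0-fold and library 3 was 14.8 to 60.4-fold above library 2. They held 1.34%, 0.0993% and 2.32% of the summed FPKM in acidified libraries 1, 2 and 3. A mixture of acidified library 2 with control material is argued against by a filter and fit without that library. There 31 transcripts were called higher, the 7 included, and the other 24 reached a median of 0.972 of their rise in acidified library 2 (lower quartile 0.619). The 7 reached 0.0192 to 0.0662, and 23 of the 24 lay above the highest of them. That gap is largely built in, since the 7 were picked for low values in this library. Only the level reached by the 24 bears on a mixture, not their distance from the 7. One shared source carried in different amounts, such as another organism on or in the thalli, may be behind the 7, and in all 7 control library 1 was the highest control library. But the SD of their log2 ratio of acidified library 1 to library 3, 0.36, lay at the 6.32 percentile of 10000 random lists of 7 abundant transcripts (median 0.65). This does not decide it, and a shared response of the alga stays open.

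Other splits of the 6 libraries into 3 and 3 gave far fewer calls: at most 1 transcript against 414, 0 components against 444 and 3 isoform shares against 22, so that 1 of the 10 splits, the real one, reached each count. With 10 splits the share cannot fall under 0.05. Each other split puts libraries of both sites in both groups, so a difference between the sites widens the spread within groups and lowers the calls. The low counts therefore do not show how many calls a grouping without any difference would give.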
